A study of Mus musculus with 26 samples.

How the data were processed

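Liver RNA of 26 male C57/Bl6 mice was hybridised to Illumina mouse BeadChips, slides that carry several arrays of probe-coated beads. Per the labels, they fall into 6 groups by thyroid state and treatment. Per the series' design text, hypothyroidism came from 2 weeks on an iodine-deficient diet, vehicle or ligand was given once by oral gavage, and RNA was taken 24 h later. The dose for mice and the clock time of tissue collection are not given in the sources used here. Age is 9 weeks in the design text and 9 months in the sample characteristics, and this was not settled. The design text counts mice per treatment, so each array was taken as 1 mouse. Cell-line arrays that the design text also mentions were not analysed here.

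Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase treatment and checked on a Bioanalyser. Biotinylated cRNA was then made with a commercial amplification kit and stained with streptavidin-Cy3. Per the submitters' processing notes, GenomeStudio and lumi were used, with no version or role given. The scanner table deposited by the authors holds, per array and probe, an average bead intensity on a linear scale, a detection p-value, the number of beads and the bead standard error, per the file headers. Its intensities were not normalized between arrays, and the lowest was 30.3. A value table deposited by the authors holds 33939 of the 45281 probes on a scale that behaves as log2. Compared with the scanner intensities, each of its columns was a rank-preserving transform of 1 array. Its column medians were 5.84 in every euthyroid array and 5.76 in every hypothyroid array, so the 2 thyroid states appear to have been quantile-normalized apart. The exact transform, any background step and the choice of probes in that table stay unknown. It was used only as an alternative, never between the control groups of the 2 states. All columns of per-sample values were matched to a sample by name, and 0 were left over.

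The main values were computed from the scanner intensities with neqc of limma 3.58.1 in R 4.3.3: background correction with negative-control statistics inferred from the detection p-values, an offset of 16, quantile normalization over all 26 arrays, and log2. The offset shrinks fold changes of dim probes. Probes were kept when their detection p was under 0.05 on at least 3 arrays, which left 20673. Gene names came from a table of the platform's annotation, in which 29213 probes of the array have 1 gene symbol, 8 have several and 16060 are unnamed here. Of the kept probes 15088 had 1 symbol, 4 had several and 5581 had none, and 15075 symbols were updated through their Entrez number. A gene was represented by its brightest kept probe, which gave 10313 genes. No reference genome was used, so no positions are given. None of the 325 pairs of arrays held identical values.

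Differences were tested with limma (lmFit, eBayes) and Benjamini-Hochberg adjustment over all kept probes, with calls at an adjusted p under 0.05. The 3 groups of each thyroid state were fitted together for T3 against control, GC-1 against control and GC-1 against T3. All 26 arrays were fitted together for the difference of each ligand's response between states (hypothyroid minus euthyroid) and for hypothyroid against euthyroid controls. Every adjusted p of a gene in the text comes from these limma fits, and errors of log2 fold changes are the fits' standard errors (SE). A probe with a detection p of 0.05 or more on every array of a group has only a bound there. Its fold change is written "at least N-fold", taken between the bright group's mean and the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among detected probes. Arrays are limited in precision by their number. On simulated data made from the real arrays, the fit recovered 76.1% of probes changed 2-fold and 28.4% of those changed 1.5-fold for T3 and 77.6% and 26.9% for GC-1 in euthyroid mice, and 49.3% and 20.9% for T3 and 58.2% and 32.8% for GC-1 in hypothyroid mice. For the differences of response it recovered 35.8% and 2.99% (T3) and 40.3% and 8.96% (GC-1).

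There were 16 gene lists and 14 lists of cell type markers. The gene lists were thyroid hormone target genes; thyroid hormone receptors, transport and metabolism; fatty acid and triglyceride synthesis; cholesterol synthesis and uptake; bile acid synthesis and sterol export; lipoproteins and their receptors; fatty acid oxidation and ketogenesis; oxidative phosphorylation; glucose and glycogen metabolism; urea cycle and amino acid metabolism; drug and xenobiotic metabolism; growth hormone signalling with sex-dependent liver genes; circadian clock; cell cycle; acute phase; and endoplasmic reticulum stress. Limma's camera tested whether the genes of a list shifted relative to all other genes, with a preset correlation of 0.01 between genes and again with an estimated correlation. Limma's fry tested whether the genes of a list moved, on balance, one way, without comparing them with other genes. Both were adjusted over the lists of 1 comparison, and lists with 2 measured members were not tested. An array's list score is the median over the list of the log2 difference from the mean of the control arrays of its state.

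The text names, for each ligand and state, up to 8 genes with the largest rise and up to 8 with the largest fall among called genes whose treated arrays all lay above, or all below, every control array. Chance gives such a separation in 0.794% of genes for 5 against 5 arrays, 5.71% for 3 against 4 and 2.86% for 4 against 4. It also names every thyroid hormone target gene, and up to 3 members per list and direction with the smallest adjusted p. Some members whose call rested on single arrays are counted but not named, a choice made after their values were seen. For the other comparisons it names up to 8 genes each way. Lists, rule, groups, models and alternatives were set before the data were examined, except where the text says otherwise.

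Per the file headers, the arrays lay on 7 slides. Slide 1 held the 5 euthyroid controls and T3 replicate 1. Slide 2 held T3 replicate 2 with GC-1 replicates 1 and 2, and slides 3, 4 and 5 each held 1 T3 and 1 GC-1 array with the same replicate number. Slide 6 held the 4 hypothyroid controls with T3 replicates 1 and 2, and slide 7 held T3 replicate 3 with the 4 GC-1 arrays. GC-1 and control arrays therefore never shared a slide, and a fit with slide as a block links them only through T3 arrays. The 2 thyroid states shared no slide, so state and slide run cannot be told apart.

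Replicate numbers were checked for pairing through the correlation of same-numbered arrays' deviations from their group means. Between euthyroid T3 and GC-1 arrays the 5 correlations were 0.214 to 0.870, all above 0.1, and 4 of these 5 pairs shared a slide. The numbers were taken to pair these 2 groups. With the replicate block, limma called 0 probes between them, as without it (969 and 725 at an unadjusted p under 0.05). Of all 25 same-numbered pairs in 1 state 10 exceeded 0.1, so no other groups were taken as paired.

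Alternatives were no background correction, the authors' value table, neqc within each thyroid state, no detection filter, slide as a fixed or as a random block (statmod 1.5.0), replicate number as a block, other sets of groups in the fit, and leaving out each array in turn. Where a range over all settings stands beside an adjusted p, it covers these alternatives. Leaving out the arrays that stand apart, intervals of GC-1 minus T3 with the replicate block, and simulations that keep same-numbered euthyroid T3 and GC-1 arrays together were chosen after seeing the data. Comparisons of T3 and GC-1 against the same controls were set beside 100 simulations of unchanged groups and beside splits of the controls. For each comparison, at most 100 splits of the same arrays, drawn with a fixed seed, were fitted. Files were read with pandas 2.3.3 (Python 3.11.15) and data.table version 1.17.8, and figures drawn with matplotlib 3.10.9.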

Results

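Transcript levels were measured in the livers of 26 mice, 1 array per mouse, in 6 groups: euthyroid mice given vehicle, T3 or GC-1 (5 mice each) and hypothyroid mice given vehicle (4), T3 (3) or GC-1 (4). T3 (triiodothyronine) is the active thyroid hormone. GC-1 (sobetirome) is a synthetic thyroid hormone analog selective for receptor beta. It carries methyl groups in place of the inner-ring iodines of T3, an isopropyl group in place of the outer-ring iodine, a methylene bridge in place of the ether oxygen, and an oxyacetic acid in place of the amino acid side chain. Among all probes of the array, 16175 to 17039 were detected on the euthyroid arrays and 12276 to 14020 on the hypothyroid arrays, whose median raw intensities were 90.6 to 109.6 and 47.1 to 70.7. Within the euthyroid mice, T3 replicate 1 and GC-1 replicate 1 stood apart, with a median correlation of 0.941 each with the other arrays of their group, against 0.974 to 0.989.

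The first comparison addressed which liver transcripts T3 changed within 24 h in euthyroid mice. Ttbk1, which encodes a tau tubulin kinase, rose by a log2 fold change of 4.08 ± 0.15 (SE, n = 5 against 5, limma adjusted p = 5.18e-10, 16.9-fold). Cyp17a1, a steroid hydroxylase and lyase, rose by 3.93 ± 0.39 (adjusted p = 4.97e-05, 15.3-fold) and Crybb3, a beta crystallin known from the lens, by 3.38 ± 0.33 (adjusted p = 4.97e-05, 10.4-fold). Ppp1r3c, which directs protein phosphatase 1 to glycogen, fell by a log2 of 3.10 (SE 0.28, adjusted p = 2.88e-05, 8.55-fold lower), and Serpina7, thyroxine-binding globulin, was lower at -2.46 ± 0.25 (adjusted p = 6.52e-05, 5.52-fold). The other genes of the largest rises were Wfdc16 at 2.44 ± 0.27, the acyl-CoA thioesterase Acot11 at 2.40 ± 0.23, Mmd2 at 2.16 ± 0.21, and Cep126 and Sspo, whose control arrays were below background, at least 3.66-fold and at least 3.43-fold. The other large falls were in Ppp1r3g, a second glycogen-targeting subunit, at -2.77 ± 0.61 (adjusted p = 0.0257), the transporter Abca8a at -2.49 ± 0.47 (adjusted p = 0.00959) and the acyl-CoA thioesterase Acot1 at -2.28 ± 0.49 (adjusted p = 0.0219). Etnppl, which breaks down ethanolamine phosphate, was at -2.46 ± 0.20, the steroid dehydrogenase Hsd17b6 at -2.32 ± 0.32 and Gm4952 at -2.15 ± 0.34. In each of these 16 genes all 5 T3 arrays lay on the same side of all 5 controls. In all, limma called 467 of 20673 probes, 291 higher and 176 lower, among them the representative probes of 283 genes (173 higher, 110 lower). Of the 12 measured thyroid hormone target genes 5 rose and 7 did not pass, and 5 rose when adjusted over the list alone. Thrsp, a lipogenic regulator, rose by 1.73 ± 0.27 (adjusted p = 0.00247), Bcl3, an inhibitor-of-kappa-B family member, by 1.56 ± 0.23 (adjusted p = 0.00159), and Gpd2, mitochondrial glycerol phosphate dehydrogenase, by 1.46 ± 0.28 (adjusted p = 0.01003). Dio1, the type 1 deiodinase, rose by 1.12 ± 0.27 (adjusted p = 0.0466) and Hr, a nuclear receptor corepressor, by 1.22 ± 0.28 (adjusted p = 0.0339). The members without a call were Klf9 at 0.29 ± 0.16, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.84 ± 0.41, Pck1 at -0.03, G6pc at -0.02, Atp2a2 at 0.12, Ppargc1a at 0.09 and Fgf21 at 0.07. Camera placed the target list above other genes (median 0.57, adjusted p = 9.47e-05, adjusted p = 0.0139 with estimated correlation). With 1 array left out, Dio1 no longer passed without control 1, 2, 3, 4 or 5, or T3 2, 3, 4 or 5 (adjusted p = 0.0506 to 0.113), nor did Hr without control 1, 2, 3 or 5, or T3 1, 3, 4 or 5 (adjusted p = 0.0602 to 0.0912). Ppp1r3g no longer passed without control 4 or 5, or T3 3, 4 or 5 (adjusted p = 0.0554 to 0.0700), nor did Acot1 without control 1 or 5 (adjusted p = 0.0519 to 0.0535).

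Among the other lists in euthyroid mice given T3, the transport list had Ttr, transthyretin, and Dio1 higher and Serpina7 lower, with Ttr at 0.87 ± 0.12 (adjusted p = 0.000734). Of its 13 members 10 did not pass, and 2 rose and 1 fell when adjusted over the list alone. Of 17 genes of fatty acid and triglyceride synthesis 2 rose, Thrsp among them (2 rose and 1 fell, adjusted over the list alone). Of 18 cholesterol genes Hsd17b7 rose by 0.83 ± 0.13 (adjusted p = 0.00251), the only one also when adjusted over the list alone. The bile acid and sterol export list had 2 of 17 higher, and 3 adjusted over the list alone. Of 19 lipoprotein genes 2 rose, among them Apoa1 at 0.57 ± 0.12 (adjusted p = 0.0248), and 3 rose and 1 fell when adjusted over the list alone. In fatty acid oxidation Acot1 fell among 22 members, and 4 fell when adjusted over the list alone. Camera placed this list below other genes (median -0.37, adjusted p = 0.0284, adjusted p = 0.807 with estimated correlation). Of 62 genes of oxidative phosphorylation 1 rose, and 2 rose when adjusted over the list alone. Glucose and glycogen genes split into Gpd2 higher and Ppp1r3c lower among 21, with 1 higher and 2 lower adjusted over the list alone. Of 22 urea cycle and amino acid genes 1 fell, with 1 higher and 3 lower adjusted over the list alone. The 44 drug metabolism genes gave 5 rises, among them the sulfotransferase Sult5a1 at 1.67 ± 0.13 (adjusted p = 8.64e-06) and the glutathione transferases Gstt3 and Gstt1 at 1.39 and 0.93. They also gave 4 falls, among them the nuclear receptor Nr1i3 at -1.75 ± 0.28 (adjusted p = 0.00309) and Cyp2c55 at -1.06. Adjusted over the list alone, 8 rose and 6 fell. Of 17 growth hormone genes Stat5a rose by 1.61 ± 0.11 (adjusted p = 3.82e-06) and 1 fell, 1 each way also when adjusted over the list alone. Of 13 clock and of 21 cell cycle genes 1 each fell, also when adjusted over the list alone. None of 19 acute phase and 16 endoplasmic reticulum stress genes passed in limma, over all probes or adjusted over the list alone. Among markers, Ttr and Apoa1 rose of 8 hepatocyte genes (2 adjusted over the list alone; camera median 0.22, adjusted p = 0.0175, adjusted p = 0.0813 with estimated correlation). Cdh1, at 0.81 ± 0.15 (adjusted p = 0.00812), rose of 6 periportal genes (1 adjusted over the list alone), and of 8 pericentral genes 1 rose and 1 fell only when adjusted over the list alone. Of 3 pancreatic acinar markers 1 rose when adjusted over the list alone. Their score was 5.81 in T3 replicate 3 and -0.14 to 0.11 in the other T3 arrays. Camera gave an adjusted p of 0.0707 or more for all lists but the targets, fatty acid oxidation and hepatocytes. Its direction differed in sign from the list's median or mean for the transport list (median 0.07, mean -0.04, camera up), and for oxidative phosphorylation, cell cycle, endoplasmic reticulum stress, pericentral, periportal and adipocyte genes. The 2 arrays that stand apart had Kupffer cell scores of -0.61 (T3 replicate 1) and -1.19 (GC-1 replicate 1). T3 replicate 1 had the highest target score of the T3 arrays, 1.05 against 0.23 to 0.72, and the lowest fatty acid oxidation score, -0.66 against -0.26 to 0.03.

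With slide as a block, which for T3 in euthyroid mice means slide 1 with 1 T3 array, 270 probes were called, 120 of them among the 467. A fit of slide 1 alone, which takes its spread from the 5 controls, called 5664. The median shifts there were 1.05 for target genes, -0.66 for fatty acid oxidation and 0.29 for hepatocyte genes. It ended 26 of the 41 calls of named genes, among them Bcl3, Gpd2, Dio1 and Thrsp (adjusted p = 0.126, all settings 0.000364 to 0.126). Leaving out control replicate 5 lowered the count to 286, and leaving out the 2 arrays that stand apart raised it to 1016. Apoa1 no longer passed without control 1, 3 or 5, or T3 2, 3, 4 or 5 (adjusted p = 0.0531 to 0.0717).

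GC-1 in euthyroid mice was tested against the same 5 controls. Crybb3 rose by 3.84 ± 0.33 (SE, n = 5 against 5, limma adjusted p = 1.78e-05, 14.3-fold), Ttbk1 by 3.74 ± 0.15 (adjusted p = 1.85e-09, 13.4-fold) and Cyp17a1 by 3.68 ± 0.39 (adjusted p = 0.000103, 12.8-fold). Ppp1r3c fell by a log2 of 3.65 (SE 0.28, adjusted p = 5.27e-06, 12.5-fold lower) and Hsd17b6 by a log2 of 2.78 (SE 0.32, 6.85-fold lower). The other large rises were in the clock output factor Dbp at 2.66 ± 0.51 (adjusted p = 0.00988), Wfdc16 at 2.35 ± 0.27, Sult5a1 at 2.12 ± 0.13, Acot11 at 2.12 ± 0.23 and the organic anion transporter Slc22a7 at 1.999 ± 0.23. The other large falls were in Abca8a at -2.66 ± 0.47 (adjusted p = 0.00585), Etnppl at -2.53 ± 0.20 and Depp1 at -1.98 ± 0.39 (adjusted p = 0.0124). Serpina7 was at -2.27 ± 0.25, the succinate receptor Sucnr1 at -2.26 ± 0.37 and Gm4952 at -2.23 ± 0.34. In each of these 16 genes all 5 GC-1 arrays lay on the same side of all 5 controls. Limma called 524 probes, 303 higher and 221 lower, and 306 genes (173 higher, 133 lower). Of the 12 target genes 3 rose, Thrsp at 1.95 ± 0.27 (adjusted p = 0.000779), Bcl3 at 1.83 ± 0.23 (adjusted p = 0.000351) and Gpd2 at 1.40 ± 0.28 (adjusted p = 0.0124), and 4 rose when adjusted over the list alone. Dio1, at 0.94 ± 0.27 (adjusted p = 0.0983), and Hr, at 0.57 ± 0.28 (adjusted p = 0.411), did not pass. Neither did Klf9 at 0.36, Cyp7a1 at 0.69 ± 0.41, Pck1 at 0.18, G6pc at -0.42, Atp2a2 at -0.02, Ppargc1a at -0.01 and Fgf21 at 0.15. Camera placed the target list above other genes (median 0.46, adjusted p = 0.00243, adjusted p = 0.0504 with estimated correlation). The target score was 0.97 in GC-1 replicate 1 and 0.26 to 0.48 in the other GC-1 arrays.

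Of the further lists after GC-1 in euthyroid mice, clock genes had 2 rises of 13, Dbp and Ciart at 1.06 ± 0.25 (adjusted p = 0.0359). Arntl, an activator of the clock, fell, at -1.71 ± 0.23 (adjusted p = 0.000675), and 6 rose and 2 fell when adjusted over the list alone. The 44 drug metabolism genes had 4 rises, among them Gstt1 at 1.203 ± 0.13 (adjusted p = 9.92e-05) and Gstt3 at 1.12, with 8 each way adjusted over the list alone. The 3 falls were the cytochromes Cyp2c29 at -1.93 ± 0.25 (adjusted p = 0.000429) and Cyp2c55 at -1.61, and Nr1i3 at -1.25 (adjusted p = 0.0269). Stat5a rose by 1.58 ± 0.11 (adjusted p = 3.35e-06) and Igfbp1, a binding protein of insulin-like growth factors, fell by a log2 of 1.91 (adjusted p = 0.000433) among 17 growth hormone genes, 1 each way also adjusted over the list alone. Ttr, at 0.91 ± 0.12 (adjusted p = 0.000425), and Serpina7 were the 2 called of 13 transport genes (2 higher and 1 lower adjusted over the list alone). Of 17 fatty acid synthesis genes Thrsp rose and 1 fell (3 each way adjusted over the list alone). Hsd17b7 rose by 0.78 (adjusted p = 0.00355) of 18 cholesterol genes (3 higher and 1 lower adjusted over the list alone). Abcg8, at 1.57 (adjusted p = 0.0195), was the 1 called of 17 bile acid genes (3 adjusted over the list alone). Apoa1, at 0.55 (adjusted p = 0.0275), was 1 of 2 that rose of 19 lipoprotein genes (3 higher and 1 lower adjusted over the list alone). In fatty acid oxidation Acot1 fell, at -1.94 ± 0.49 (adjusted p = 0.0493), and 4 of 22 fell when adjusted over the list alone. Camera placed the list below other genes (median -0.33, adjusted p = 0.0129, adjusted p = 0.577 with estimated correlation). No gene of the oxidative phosphorylation (62), cell cycle (21) or endoplasmic reticulum stress (16) lists passed in limma. Adjusted over the list alone, 1 of the last fell. Gpd2 rose and Ppp1r3c fell of 21 glucose genes (1 each way adjusted over the list alone). Oat, at -1.05 (adjusted p = 0.0137), was 1 of 2 that fell of 22 urea cycle and amino acid genes (1 higher and 3 lower adjusted over the list alone). Of 19 acute phase genes 1 rose, also adjusted over the list alone. Among markers Ttr and Apoa1 rose of 8 hepatocyte genes (2 adjusted over the list alone), Oat fell of 8 pericentral genes (1 each way adjusted over the list alone), and 1 of 3 adipocyte genes rose when adjusted over the list alone. Camera called no further list (lowest adjusted p = 0.0681). Its direction differed in sign from median or mean for lipoproteins (median -0.02, mean 0.01), growth hormone, cell cycle, endoplasmic reticulum stress, pericentral and pancreatic acinar genes. With slide as a block, linked through T3 arrays, 97 probes were called, 57 of them among the 524. The shifts were 1.03 for target genes and -1.11 for fatty acid oxidation. It ended 27 of the 38 calls of named genes, among them Arntl, Serpina7, Dbp and Thrsp (adjusted p = 0.151, all settings 0.000113 to 0.151). The count was 340 without control replicate 1, 345 without control replicate 5, and 889 without the 2 arrays that stand apart. Ciart no longer passed without control 1, 2, 3, 4 or 5, or GC-1 1, 3 or 4 (adjusted p = 0.0692 to 0.0964), nor did Nr1i3 without control 1, 3 or 5, or GC-1 2, 3, 4 or 5 (adjusted p = 0.0504 to 0.0763). Abcg8 no longer passed without control 4 or 5, or GC-1 3 (adjusted p = 0.0507 to 0.0574), nor did Apoa1 without control 1, 3 or 5, or GC-1 1 or 3 (adjusted p = 0.0617 to 0.0772). Acot1 no longer passed without control 1, 2, 4 or 5, or GC-1 2, 3, 4 or 5 (adjusted p = 0.0837 to 0.124).

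**Figure D1:**
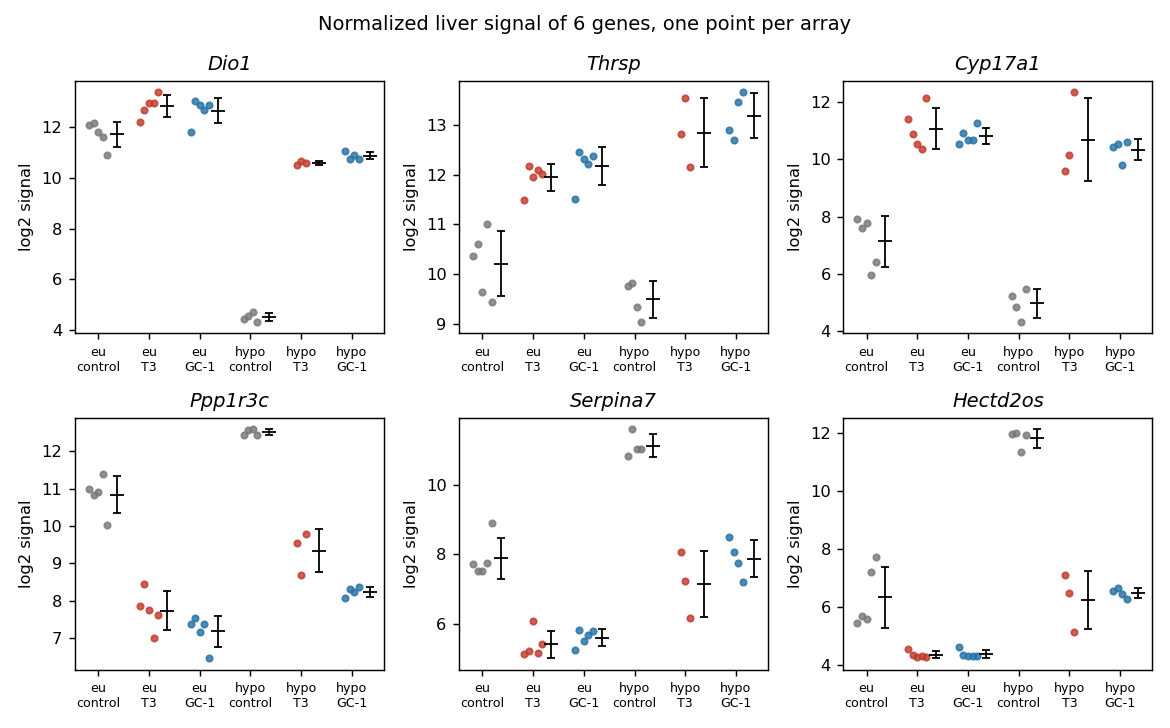
Normalized log2 signal of Dio1, Thrsp, Cyp17a1, Ppp1r3c, Serpina7 and Hectd2os in the 6 groups, 1 point per array, with the group mean and SD in black. Dio1 was at least 38.3-fold and at least 46.8-fold higher after T3 and GC-1 than in its hypothyroid controls, which were below background.

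T3 was next compared with vehicle in hypothyroid mice (3 against 4 arrays). Dio1 was at least 38.3-fold higher (limma adjusted p = 3.79e-10), with all 4 controls below background. Cyp17a1 rose by 5.71 ± 0.54 (SE, adjusted p = 0.000196, 52.5-fold) and Gpcpd1, a glycerophosphocholine phosphodiesterase, by 4.11 ± 0.19 (adjusted p = 7.56e-07, 17.3-fold). Hectd2os, an antisense transcript of Hectd2, fell by a log2 of 5.57 (SE 0.37, adjusted p = 1.75e-05, 47.5-fold lower), and Acot1 by a log2 of 4.86 (SE 0.27, 29.1-fold lower). Crybb3, at least 25.8-fold, the pancreatic elastase Cela2a, at least 10.2-fold, and Wfdc12, at least 10.6-fold, rose from controls below background, and the mitochondrial carrier Slc25a45 rose by 3.49 ± 0.26 (11.2-fold). Gas7, at least 12.8-fold lower, and the thioesterase Acot3, at least 10.0-fold lower, fell below background. Serpina7 was at -3.96 ± 0.41 (adjusted p = 0.000309), the carbonyl reductase Cbr3 at -3.63 ± 0.27, Etnppl at -3.48 ± 0.54 and Gm4956 at -3.39 ± 0.48. In the 16 genes of the largest changes, Thrsp among them, all 3 T3 arrays lay on the same side of all 4 controls. Limma called 974 probes, 504 higher and 470 lower, and 566 genes (288 higher, 278 lower). Of the 12 target genes 7 rose and 9 rose when adjusted over the list alone. Thrsp rose by 3.34 ± 0.33 (adjusted p = 0.000269, 10.1-fold), Bcl3 by 2.73 ± 0.32 (adjusted p = 0.000633), and Gpd2 by 2.62 ± 0.22 (adjusted p = 7.41e-05). The hepatic hormone Fgf21 rose by 2.03 ± 0.26 (adjusted p = 0.00118), Cyp7a1 by 2.94 ± 0.60 (adjusted p = 0.0182), and Hr by at least 6.07-fold. Pck1, at 1.04 ± 0.37 (adjusted p = 0.172), and G6pc, at 0.73 (adjusted p = 0.314), both enzymes of gluconeogenesis, Atp2a2 at 0.71, Klf9 at 0.13 and Ppargc1a at 0.06 did not pass. The target list's median was 2.33, or 2.32 with Dio1 and Hr at their bounds (camera adjusted p = 4.53e-13, adjusted p = 0.00209 with estimated correlation). Cyp7a1 no longer passed without T3 1 or 2 (adjusted p = 0.0522 to 0.0678).

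In the lists of hypothyroid mice given T3, 14 of 44 drug metabolism genes fell, among them the flavin monooxygenase Fmo5 at -1.29 ± 0.17 (adjusted p = 0.00163), the glutathione transferase Gstm4 at -1.45 ± 0.21 (adjusted p = 0.00239) and Cbr3. Another 3 rose, among them the sulfotransferase Sult1d1 at 1.07 (adjusted p = 0.0108) (3 rose and 18 fell, adjusted over the list alone). Camera placed this list below other genes (median -0.63, adjusted p = 7.24e-06, adjusted p = 0.366 with estimated correlation), with scores of -0.53, -0.20 and -0.83 in T3 replicates 1, 2 and 3. Of 18 cholesterol genes 3 rose, also when adjusted over the list alone, among them the squalene epoxidase Sqle at 1.18 ± 0.16 (adjusted p = 0.00152). Camera gave this list a median of 0.32 (adjusted p = 0.00638, adjusted p = 0.366 with estimated correlation). Oxidative phosphorylation had 3 of 62 higher, also adjusted over the list alone, among them Ndufa5 at 0.69 ± 0.13 (adjusted p = 0.00989). Its median was 0.14 (camera adjusted p = 0.00123, adjusted p = 0.379 with estimated correlation). In fatty acid oxidation 2 fell of 22, Acot1 among them, and 4 adjusted over the list alone. The median was -0.32 (camera adjusted p = 0.00291, adjusted p = 0.379 with estimated correlation). Acute phase genes gave 1 rise, hepcidin (Hamp) at 0.89 (adjusted p = 0.0494), of 19 and 4 adjusted over the list alone. Their median was 0.60 (camera adjusted p = 0.000189, adjusted p = 0.379 with estimated correlation). Endoplasmic reticulum stress genes gave 1 rise and 1 fall of 16 (3 and 1 adjusted over the list alone). Camera gave them a median of 0.61 (adjusted p = 0.00227, adjusted p = 0.396 with estimated correlation). In both lists the score was highest in T3 replicate 3, at 1.37 against 0.37 and 0.19, and at 1.03 against 0.28 and 0.27. The neutrophil marker S100a8 rose by 2.32 ± 0.53 (adjusted p = 0.0309), 1 of 2 measured, also adjusted over the list alone. Neutrophil scores were 1.27, 1.12 and 1.59 in the T3 arrays against -0.55 to 0.66 in the GC-1 arrays.

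The bile acid list in hypothyroid mice given T3 had 3 of 17 higher, among them Cyp7a1 and Cyp7b1 at 1.48 ± 0.23 (adjusted p = 0.00389). The receptor Nr5a2 was lower, at -0.87 (adjusted p = 0.00509) (4 and 1 adjusted over the list alone). Of 19 lipoprotein genes Apof rose by 0.87 (adjusted p = 0.00865) and the receptor Vldlr fell, at -2.65 ± 0.42 (adjusted p = 0.00456) (1 each way adjusted over the list alone). The transport list had 2 higher, Dio1 among them, and Serpina7 lower of 13 (3 and 2 adjusted over the list alone). Fatty acid synthesis had 2 higher, Thrsp among them, of 17 (2 adjusted over the list alone). Glucose and glycogen metabolism had Gpd2 higher and 2 lower, among them Ppp1r3c at -3.16 ± 0.21 (adjusted p = 2.05e-05), of 21 (3 and 5 adjusted over the list alone). Of 22 urea cycle and amino acid genes 3 fell, among them the aminotransferase Oat at -1.45 ± 0.24 (adjusted p = 0.00541) and cystathionine gamma-lyase (Cth) at -2.61 ± 0.44 (adjusted p = 0.00637) (5 adjusted over the list alone). Growth hormone genes gave 2 rises of 17, Stat5a at 2.54 ± 0.24 (adjusted p = 0.000171) and Cyp7b1 (2 higher and 1 lower adjusted over the list alone). Clock genes gave 1 fall of 13 (1 adjusted over the list alone). No cell cycle gene of 21 passed in limma, nor did any when adjusted over the list alone. Pericentral markers had 3 of 8 lower, among them Oat and Slc1a2 at -1.18 (adjusted p = 0.00581) (4 adjusted over the list alone). Their median was -0.79 (camera adjusted p = 0.00500, adjusted p = 0.366 with estimated correlation), and their score was -1.22 in T3 replicate 3 against -0.41 and -0.45. Of 8 hepatocyte markers the probe of albumin (Alb) was lower, at -1.06 ± 0.18 (adjusted p = 0.00722) (1 adjusted over the list alone). It was below background in euthyroid controls although albumin is abundant in liver, so whether it reads the main transcript is open. Of 6 periportal markers 1 fell (3 higher and 1 lower adjusted over the list alone). Erythroid markers gave 2 falls of 3 when adjusted over the list alone (camera median -0.50, adjusted p = 0.0290, adjusted p = 0.366 with estimated correlation), with scores of -0.61 to -0.50. Of 3 pancreatic acinar markers Cela2a rose, also adjusted over the list alone, and Cpb1 and Ctrb1 were at 0.16 and 0.01. Camera called no other list, and its direction differed in sign from median or mean for the transport, lipoprotein, clock, hepatocyte, stellate, and T and NK cell lists. With slide as a block 1003 probes were called, 706 of them among the 974. Within slide 6 (2 T3 arrays against 4 controls) limma called 413. The shifts within slide 6 were 2.28 for target, -0.39 for drug metabolism, 0.29 for cholesterol, 0.23 for oxidative phosphorylation and -0.44 for fatty acid oxidation. They were 0.26 for acute phase, 0.30 for endoplasmic reticulum stress, -0.43 for pericentral and -0.50 for erythroid genes.

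For T3 in hypothyroid mice, Hamp no longer passed without control 1, 2, 3 or 4, or T3 1, 2 or 3 (adjusted p = 0.0517 to 0.130), nor did S100a8 without control 1, 2, 3 or 4, or T3 1, 2 or 3 (adjusted p = 0.0517 to 0.0911).

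GC-1 in hypothyroid mice was tested against the same 4 controls (4 against 4 arrays). Dio1 was at least 46.8-fold higher (limma adjusted p = 9.72e-11), Cyp17a1 rose by 5.37 ± 0.50 (SE, adjusted p = 0.000108, 41.3-fold), and Cyp7a1 by 3.89 ± 0.56 (adjusted p = 0.00169, 14.8-fold). Hectd2os fell by a log2 of 5.33 (SE 0.34, adjusted p = 7.13e-06, 40.2-fold lower), and Ppp1r3c by a log2 of 4.26 (SE 0.20, 19.2-fold lower). The other large rises were in Cela2a at least 16.2-fold and Crybb3 at least 10.4-fold, from controls below background, Gpcpd1 at 3.90 ± 0.17 (14.9-fold), the uridine phosphorylase Upp2 at 3.83 ± 0.34 (14.2-fold) and Acot11 at 3.77 ± 0.31 (13.7-fold). The other large falls were in Acot1 at -4.64 ± 0.25, Gas7 at -3.71 ± 0.18, Acot3, which fell below background, Serpina7 at -3.24 ± 0.38, Cbr3 at -3.15 ± 0.25 and Gm4956 at -2.78 ± 0.45. In each of these 16 genes all 4 GC-1 arrays lay on the same side of all 4 controls. Limma called 1577 probes, 910 higher and 667 lower, and 907 genes (517 higher, 390 lower). Of the 12 target genes 8 rose, and 9 when adjusted over the list alone. Beside Dio1 and Cyp7a1 these were Thrsp at 3.68 ± 0.31 (adjusted p = 6.05e-05, 12.8-fold), Bcl3 at 2.78 ± 0.29 (adjusted p = 0.000249), and Gpd2 at 2.77 ± 0.20 (adjusted p = 2.05e-05), as well as Fgf21 at 1.90 ± 0.24 (adjusted p = 0.000746), Pck1 at 1.91 ± 0.35 (adjusted p = 0.00692) and Hr at least 3.51-fold. G6pc, at 1.05 ± 0.32 (adjusted p = 0.0712), Klf9 at 0.13, Atp2a2 at 0.16 and Ppargc1a at -0.17 did not pass over all probes. The list's median was 2.11, or 1.91 with Dio1 and Hr at their bounds (camera adjusted p = 7.50e-11, adjusted p = 0.00403 with estimated correlation).

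Oxidative phosphorylation genes rose in 11 of 62 cases after GC-1 in hypothyroid mice (17 adjusted over the list alone), among them Ndufa5 at 0.73 ± 0.12 (adjusted p = 0.00320), Cycs at 0.88 ± 0.16 (adjusted p = 0.00741) and Ndufb4 at least 1.45-fold. Camera gave a median of 0.25 (adjusted p = 4.06e-07, adjusted p = 0.353 with estimated correlation). Fatty acid oxidation genes fell in 5 of 22 cases (8 adjusted over the list alone), among them Acot1 and the medium-chain dehydrogenase Acadm at -0.75 (adjusted p = 0.00958). The median was -0.14 (camera adjusted p = 0.0272, adjusted p = 0.615 with estimated correlation). The bile acid list had 4 of 17 higher, among them Cyp7b1 at 1.497 ± 0.21 (adjusted p = 0.00160) and Cyp27a1 at 1.004 (adjusted p = 0.00661), and Nr5a2 lower at -0.79 (adjusted p = 0.00421) (7 and 1 adjusted over the list alone). Its median was 0.33 (camera adjusted p = 0.0405, adjusted p = 0.542 with estimated correlation). Fatty acid synthesis had Thrsp and the carbohydrate-response factor Mlxipl, at 1.13 (adjusted p = 0.00976), higher of 17 (3 adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.0405, adjusted p = 0.615 with estimated correlation). Of 18 cholesterol genes 5 rose, also adjusted over the list alone, among them Sqle at 0.77 (adjusted p = 0.00858) and Idi1 at 1.29 (adjusted p = 0.0152). Drug metabolism had 6 of 44 higher, among them Papss2 at 2.65 ± 0.35 (adjusted p = 0.000960) and Sult5a1 at least 2.55-fold. It had 9 lower, among them Cbr3, Aox1 at -1.18 ± 0.13 (adjusted p = 0.000345) and the quinone reductase Nqo1 at -1.43 ± 0.21 (adjusted p = 0.00174) (7 and 12 adjusted over the list alone). The clock list had 3 of 13 higher, among them Per3 at least 1.41-fold and Tef at 1.21 ± 0.21 (adjusted p = 0.00621). The 2 lower were Rora at -0.99 (adjusted p = 0.00563) and Arntl at least 1.46-fold lower (4 and 2 adjusted over the list alone). Lipoprotein genes gave Apof, at 0.95 (adjusted p = 0.00231), and Scarb1, at least 1.53-fold, higher and 2 lower of 19 (3 and 2 adjusted over the list alone). The transport list had Dio1 higher and Serpina7 lower of 13 (3 and 2 adjusted over the list alone). Glucose genes had Pck1 and Gpd2 higher and Ppp1r3c lower of 21 (4 and 6 adjusted over the list alone). Of 22 urea cycle and amino acid genes 1 rose and 3 fell, among them Oat at -1.19 (adjusted p = 0.00765) and Nags at -0.72 (adjusted p = 0.00619) (2 and 5 adjusted over the list alone). Growth hormone genes gave 3 rises of 17, among them Stat5a at 2.55 ± 0.22 (adjusted p = 6.53e-05) (3 adjusted over the list alone). Cell cycle genes gave 1, Cenpa at 1.12 (adjusted p = 0.00854), of 21 (1 adjusted over the list alone). Acute phase genes gave 1 of 19, which did not pass when adjusted over the list alone. Endoplasmic reticulum stress genes gave 1 fall, Trib3 at -1.34 (adjusted p = 0.00424), of 16 (2 higher and 1 lower adjusted over the list alone). Among markers 3 of 6 periportal genes rose, among them Cdh1 at 1.31 (adjusted p = 0.00541) and Pck1 (3 higher and 1 lower adjusted over the list alone). Of 8 pericentral genes 1 rose and 3 fell, among them Axin2 at -1.53 (adjusted p = 0.0116) (1 and 4 adjusted over the list alone). Of 8 endothelial genes 1 fell, also adjusted over the list alone. The 3 erythroid genes fell only when adjusted over the list alone (camera median -0.64, adjusted p = 0.0405, adjusted p = 0.353 with estimated correlation), with scores of -0.65 to -0.25. Cela2a rose among 3 pancreatic acinar genes, also adjusted over the list alone. No hepatocyte marker of 8 passed in limma. Camera called no other list, and its direction differed in sign from median or mean for cell cycle, cholangiocyte and pancreatic acinar genes.

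With slide as a block, linked through T3 replicate 3, 1279 probes were called for GC-1 in hypothyroid mice, 481 of them among the 1577. The shifts were 1.81 for target, 0.46 for oxidative phosphorylation, -0.87 for fatty acid oxidation, 0.88 for bile acid, 1.23 for fatty acid synthesis and -0.47 for erythroid genes. It ended 32 of the 62 calls of named genes, among them Serpina7, Acot3, Fgf21, Pck1 and Hr (adjusted p = 0.436, all settings 0.00521 to 0.436), and slide as a random block ended 14. The count was 2538 without control replicate 1, 1027 without control replicate 2, and 989, 978 and 985 without GC-1 replicates 1, 3 and 4. Arntl no longer passed without control 1, 2 or 3, or GC-1 1, 2, 3 or 4 (adjusted p = 0.0573 to 0.0991). Kupffer (9 measured), stellate (10), cholangiocyte (3), and T and NK cell (4) markers, and B cell (2) and skeletal muscle (2) markers, gave no call in limma for either ligand in either state, over all probes or adjusted over the list alone. Endothelial, erythroid and neutrophil markers gave none in euthyroid mice. Unadjusted p-values under 0.05 over all probes numbered 2707, 2784, 3479 and 4561 in the 4 comparisons.

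**Figure D2:**
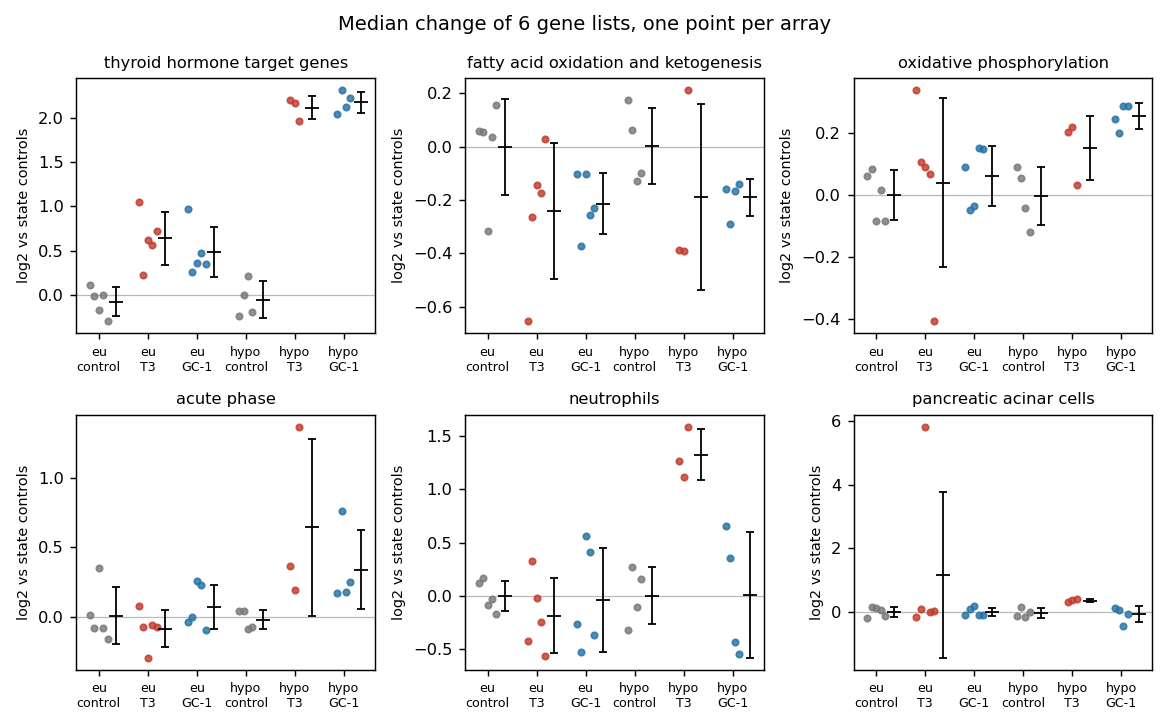
Median log2 difference from the controls of the same state for 6 gene lists, 1 point per array, with the group mean and SD in black. Target gene scores were 1.96 to 2.31 in the treated hypothyroid mice and 0.23 to 1.05 in the treated euthyroid mice.

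GC-1 and T3 were compared directly within each state, at 1 time and at doses not known here. In euthyroid mice the largest difference among the named genes was in Dbp, which was 1.80 (95% interval 0.71 to 2.88) higher on the log2 scale after GC-1. The repressor Ciart differed by 0.85 (0.31 to 1.38), Arntl by -1.27 (-1.76 to -0.77), Cyp2c29 by -0.86 (-1.39 to -0.33) and Hr by -0.65 (-1.26 to -0.05). These intervals exclude 0, but no difference passed the adjustment over all probes: limma called 0, with 725 at an unadjusted p under 0.05 and a lowest adjusted p of 0.557. The interval included 0 for Thrsp, 0.23 (-0.35 to 0.80), Dio1, -0.18 (-0.76 to 0.41), Cyp17a1, -0.25 (-1.08 to 0.57), and Gpd2, -0.07 (-0.66 to 0.53). Of 59 named genes 40 had an interval within 2-fold either way, and of the 674 probes called for T3 or GC-1 628 did (93.2%). In hypothyroid mice S100a8 was -1.89 (-3.06 to -0.73) after GC-1 relative to T3, Upp2 1.44 (0.63 to 2.25), Crybb3 -1.31 (-2.35 to -0.28), Ppp1r3c -1.10 (-1.57 to -0.63) and Dio1 0.29 (0.01 to 0.57). Limma again called 0 probes, with 2123 at an unadjusted p under 0.05 and a lowest adjusted p of 0.202. The interval included 0 for Thrsp, 0.34 (-0.40 to 1.07), Cyp7a1, 0.95 (-0.38 to 2.28), Hr, -0.79 (-1.62 to 0.04), and Gpd2, 0.15 (-0.33 to 0.63). Of 82 named genes 44 and of 1831 called probes 1386 (75.7%) had an interval within 2-fold. These limits do not show that the compounds act alike: unadjusted intervals excluded 0 for 125 and 550 called probes. Chance gives some, and slide and ligand mix in hypothyroid mice. Euthyroid intervals with the replicate block were added after the data were seen. They lay within 2-fold for 634 called probes and 43 named genes, and excluded 0 for 148 probes. The target list differed by a median of -0.08 in euthyroid and 0.10 in hypothyroid mice (camera adjusted p = 0.578 and 0.735). In euthyroid mice camera placed clock genes, median 0.41, and acute phase genes, median 0.18, higher after GC-1 (adjusted p = 0.0133 each, adjusted p = 0.708 with estimated correlation). In limma 4 clock genes were higher and 1 lower adjusted over the list alone. In hypothyroid mice camera placed drug metabolism (median 0.36, adjusted p = 3.70e-05) and oxidative phosphorylation (median 0.10, adjusted p = 0.0230) higher. Acute phase genes were lower (median -0.32, adjusted p = 0.00443). T3 replicates 1 and 2 scored within the GC-1 range, and T3 replicate 3 lay 0.606 above it. With estimated correlation adjusted p was 0.460, 0.510 and 0.510. Camera's direction differed in sign from median or mean for 5 lists in euthyroid mice, among them bile acid genes, and for 3 in hypothyroid mice, among them fatty acid oxidation.

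With slides 2 to 5 as blocks limma called 0 probes between GC-1 and T3 in euthyroid mice (527 at an unadjusted p under 0.05). Slide 2, with 2 GC-1 arrays and 1 T3 array, leaves 1 residual degree of freedom (0 called by limma, 23 unadjusted), which decides nothing, and slides 3, 4 and 5, with 1 of each, leave none. The clock list shifted by 0.48 with the block and by 0.67, 0.51, 0.32 and -0.08 on slides 2, 3, 4 and 5. The target list shifted by 0.11, -0.13, 0.09 and -0.30, and the acute phase list by 0.11, 0.60, 0.30 and 0.07. In hypothyroid mice the slide block rests on slide 7, with T3 replicate 3 as its only T3 array. Shifts on slide 7 were 0.08 for target, 0.67 for drug metabolism, 0.20 for oxidative phosphorylation, -1.14 for acute phase and -0.17 for clock genes. Leaving out hypothyroid T3 replicate 2 gave 1 call in place of 0.

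The fold changes of GC-1 and T3 share their controls. In euthyroid mice they correlated at 0.840 over all probes, beside a mean of 0.438 (-0.321 to 0.902) in simulations of unchanged groups against the same controls, and at 0.640 with the controls split between the ligands. The covariance was 0.0827 against 0.0207 simulated (-0.0124 to 0.0863), a difference of 0.0620, and 0.0710 with split controls. The same sign was seen in 77.1% of probes against 65.9% simulated (42.2% to 83.5%). Those simulations leave out the shared deviations of same-numbered T3 and GC-1 arrays. With them the simulated values were 0.650 (0.148 to 0.928), 0.0337 (0.00294 to 0.115), a difference of 0.0491, and 72.2% (53.4% to 86.7%). All observed euthyroid values lay within these ranges, so unchanged groups can give as much. In hypothyroid mice the correlation was 0.792 against 0.421 simulated (-0.223 to 0.858) and 0.573 with split controls. Its covariance was 0.170 against 0.0261 (-0.0103 to 0.0911), a difference of 0.144, and 0.139 with split controls, and the same sign was seen in 72.3% against 64.6% (43.8% to 83.1%). Called for both were 195 probes higher and 122 lower in euthyroid mice (4.27 and 1.88 if independent). In hypothyroid mice 399 were higher and 321 lower (22.2 and 15.16). With split controls, fewer per ligand, calls for both fell from 317 to a mean of 86.4 and from 720 to 351. Calls for T3 fell to 172 and 610, and for GC-1 to 198 and 1060. Over probes called for either ligand, the slope of the GC-1 on the T3 response was 1.04 in euthyroid mice (0.900 to 1.204 with split controls) and 1.06 in hypothyroid mice (1.005 to 1.12). Their directions matched in 672 of 674 and 1784 of 1831. With slide as a block the hypothyroid slope was 1.80, through T3 replicate 3.

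Whether the responses differed between the thyroid states was tested on the difference itself, hypothyroid minus euthyroid. For T3 the deiodinase Dio1 had the largest positive difference, a fitted 4.96 ± 0.35 (adjusted p = 6.20e-09), which is no exact size because its hypothyroid controls were below background. Slc25a45 differed by 2.07 ± 0.28 (adjusted p = 0.000207), the peroxisomal hydrolase Nudt7 by 2.32 ± 0.27 (adjusted p = 2.08e-05) and the major urinary protein Mup6 by 2.30 ± 0.34 (adjusted p = 0.000661). Negative differences, of which only that of Cbr3 rests on groups that were all above background, were found for Hectd2os at -3.59 ± 0.54 (adjusted p = 0.000708), Cbr3 at -3.35 ± 0.30 (adjusted p = 3.09e-07), Osbpl3 at -2.99 ± 0.35 (adjusted p = 1.78e-05) and Tulp2 at -2.07 ± 0.22 (adjusted p = 3.48e-06). Gas7 was at -3.51 and Acot3 at -3.03. These too are fitted values with no exact size. Limma called 81 probes, 42 higher and 39 lower, in 48 genes. Of the 12 target genes 1 passed, and 7 were higher when adjusted over the list alone (camera median 1.17, adjusted p = 3.81e-11, adjusted p = 8.90e-06 with estimated correlation). For GC-1, Dio1 had a fitted difference of 5.43 ± 0.34 (adjusted p = 3.06e-10), Cyp7a1 3.20 ± 0.70 (adjusted p = 0.0200), Upp2 2.98 ± 0.43 (adjusted p = 0.000343), Snai3 2.27 ± 0.24 (adjusted p = 3.12e-06), Nudt7 2.31 and Mup6 2.51. Hectd2os was at -3.38 ± 0.52 (adjusted p = 0.000786), Cbr3 at -2.83, Gas7 at -2.73, Osbpl3 at -2.37, Hectd2 at -2.22 and Tulp2 at -2.12. Of these, Dio1, Snai3, Hectd2os, Osbpl3 and Tulp2 were below background in at least 1 of the groups compared and have no exact size. Limma called 219 probes, 147 higher and 72 lower, in 108 genes, with 3 of 12 target genes higher and 9 adjusted over the list alone (camera median 1.60, adjusted p = 3.73e-10, adjusted p = 1.78e-05 with estimated correlation). Thrsp, a target gene, was at 1.72 ± 0.42 (adjusted p = 0.0400). Thrsp no longer passed without euthyroid control 1, 2 or 4, or euthyroid GC-1 1, 3, 4 or 5, or hypothyroid control 3 or 4, or hypothyroid GC-1 1, 3 or 4 (adjusted p = 0.0512 to 0.104). For T3, Acot3 no longer passed without hypothyroid control 4 (adjusted p = 0.0505, all settings 0.000227 to 0.457). The highest was with the authors' value table. The slide block ended 18 of the 27 GC-1 calls of named genes, among them Snai3, Mup6, Hectd2os, Cbr3, Osbpl3 and Hectd2, and slide as a random block 13, among them Cyp7a1. Of 100 splits of the arrays, 7 for T3 and 6 for GC-1 gave as many calls, the real one included.

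Among further lists, camera placed drug metabolism lower in the difference of T3 responses, with 2 of 44 lower and 8 adjusted over the list alone (median -0.40, adjusted p = 1.41e-06, adjusted p = 0.0725 with estimated correlation). Acute phase genes were higher, 5 of 19 adjusted over the list alone (median 0.67, adjusted p = 7.77e-07, adjusted p = 0.160 with estimated correlation). So were endoplasmic reticulum stress genes, 2 of 16 adjusted over the list alone (median 0.57, adjusted p = 8.76e-05, adjusted p = 0.141 with estimated correlation). Both lists had their highest scores in hypothyroid T3 replicate 3, 1.37 and 1.03. Hepatocyte markers were lower, Ttr at -0.90 (adjusted p = 0.0213) and the Alb probe at a fitted -1.17 (adjusted p = 0.00391) (3 of 8 adjusted over the list alone). That probe, below background in the euthyroid groups, gives no exact size and may not read the main transcript. Ttr no longer passed without hypothyroid control 4, or hypothyroid T3 2 (adjusted p = 0.0543 to 0.0577). The markers' median was -0.31 (camera adjusted p = 0.00348, adjusted p = 0.0684 with estimated correlation). Lower too were pericentral markers, 3 of 8 adjusted over the list alone (adjusted p = 0.00348, adjusted p = 0.192 with estimated correlation). Oxidative phosphorylation was higher for both ligands (medians 0.17 and 0.18, adjusted p = 0.00297 and 0.000228, adjusted p = 0.663 and 0.714 with estimated correlation). For GC-1 7 of 62 were higher adjusted over the list alone. For GC-1 camera also placed fatty acid synthesis (median 0.35, adjusted p = 0.00770, adjusted p = 0.714 with estimated correlation) higher. The same held for growth hormone genes (median 0.52, adjusted p = 0.0310, adjusted p = 0.356 with estimated correlation) and periportal markers (median 0.52, adjusted p = 0.0318, adjusted p = 0.227 with estimated correlation). Camera's direction differed in sign from median or mean for 7 lists for each ligand, among them lipoproteins for T3 and drug metabolism for GC-1. Because the states shared no slide, each difference compares slide runs as well as states, and brightness also differed between them. Counts with other settings ran from 34 with the authors' value table to 214 with slide as a block for T3. They ran from 71 with slide as a random block to 833 without hypothyroid control replicate 1 for GC-1, where leaving out GC-1 replicates 3 and 4 gave 131 and 142.

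Between hypothyroid and euthyroid controls limma called 12007 of 20673 probes, 5816 higher and 6191 lower in hypothyroid mice (4 against 5 arrays), but state and slide run cannot be told apart here, and hypothyroid arrays were dimmer. Dio1 was at least 83.5-fold lower (adjusted p = 1.17e-16). Bcl3 at -1.28 ± 0.27, Cyp7a1 at -1.87 ± 0.49 (adjusted p = 0.00226) and Pck1 at -3.27 ± 0.44 (adjusted p = 8.17e-07) were lower as well. Hectd2os at 5.47 ± 0.36, Cbr3 at 5.42 ± 0.20, Nqo1 at 3.61 ± 0.18, Serpina7 at 3.23 ± 0.32 and Ppp1r3c at 1.68 ± 0.26 were higher. Of the 12 target genes 7 were lower, also adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.0905 with estimated correlation). Kupffer cell markers were lower in 7 of 9 cases, among them Adgre1 at -3.08 ± 0.28 and Csf1r at -1.84 ± 0.25 (camera adjusted p = 0.0294, adjusted p = 0.986 with estimated correlation). The probe of Alb was below background in euthyroid controls, at least 4.28-fold below its level in hypothyroid ones. Camera's direction differed in sign from median or mean for fatty acid synthesis, lipoproteins, cell cycle and endothelial genes.

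Fry was run on the same 27 lists. In euthyroid mice it called 2 lists for T3 and 3 for GC-1, of which camera had not called hepatocyte genes (fry adjusted p = 0.000567, up) and glucose genes (adjusted p = 0.0124, down) after GC-1. In hypothyroid mice it called 9 for T3 and 10 for GC-1, of which camera had not called transport genes (adjusted p = 0.000776 and 0.000201, up), pancreatic acinar genes (adjusted p = 0.000776 and 0.000555, up) and glucose genes (adjusted p = 0.0262 and 0.0207, down), nor, for GC-1, growth hormone (adjusted p = 0.0346) and periportal genes (adjusted p = 0.00302), both up. The medians of the transport list after T3 and the acinar list after GC-1 were below 0, at -0.03 and -0.12. Between the ligands fry called 0 lists in either state (1 and 5 at an unadjusted p under 0.05). It called 3 for the difference of T3 responses, 4 for that of GC-1 responses, transport genes (adjusted p = 0.0389, up) among them, and 14 between the controls, 12 of them not called by camera. Fry did not share camera's calls of fatty acid oxidation in euthyroid mice, 3 and 1 of camera's for T3 and GC-1 in hypothyroid mice, and 4 and 2 for the differences of response.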

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

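The test on probe pairs for the euthyroid arrays, the slide test for hypothyroid T3 replicate 3, and the slide tests by state and the time-of-day test for the clock genes were chosen only after the result was seen.

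Euthyroid T3 replicate 1 and GC-1 replicate 1 lay far from the other arrays of their groups, with a median correlation of 0.941 each against 0.974 to 0.984 and 0.987 to 0.989, and their deviations from the group medians correlated at 0.869, against at most 0.289 for pairs of the other euthyroid arrays. A slide effect is argued against, because GC-1 replicate 1 and T3 replicate 2, on the same slide, had deviations that correlated at -0.0820. RNA quality, or probe position within the transcript, stays open: the deviations of the 2 brightest probes of a gene correlated at 0.385 on average over 3369 genes, below the 0.736 of the T3 response in hypothyroid mice but within the 0.239 to 0.656 of the other euthyroid arrays. No biological explanation was tested: the labels give both mice replicate number 1 but not what a number stands for. These arrays may carry a change that is neither the ligand's nor the slide's, and without them the counts were 1016 and 889 in place of 467 and 524.

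Hypothyroid T3 replicate 3 had an acute phase score 0.606 above the highest of the 4 GC-1 arrays on its slide (1.37 against 0.76), which leaves a slide effect open, since the slide holds no other T3 or control array. Blood left in the sample is argued against, because its erythroid score lay -0.110 from the higher of the other 2 T3 arrays. RNA quality stays open at a probe pair correlation of 0.557, between the bounds set for the test. No biological explanation was tested.

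The clock list lay higher after GC-1 than after T3 in euthyroid mice by camera (adjusted p = 0.0133, lost with an estimated correlation at adjusted p = 0.708 and by fry at adjusted p = 0.778), and in hypothyroid mice it did not pass (adjusted p = 0.0685). In euthyroid mice slide is argued against as the whole cause, since within slides 2 to 5 the differences had a slope of 1.11 on the full ones (0.795 to 1.51 on single slides) and the list's median was 0.48 against 0.41 in full, although it was -0.08 on slide 5. In hypothyroid mice slide stays open, because slide 7 holds 1 T3 array (slope 1.10, median -0.17 against 0.84 in full). Collection of the tissue at different times of day for the 2 ligands is a candidate explanation: over the 13 clock genes the GC-1 minus T3 differences of the 2 states correlated at r = 0.691 (permutation p = 0.00375, Spearman 0.769, across genes, which are not independent replicates), at 0.472 without the 2 genes farthest from the median, and 9 of 13 had the same sign. An effect of the ligand itself on the clock predicts the same correlation, and collection times are not given in the sources used here, so both stay open.

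Single arrays lay far from the others of their group in 32 of 332 groups of 4 or 5 arrays tested, where chance gives about 1 in 20, or 16.6. Among 25 groups of array measures there were 6. Median beads per probe were 43 in euthyroid GC-1 replicate 5 (others 42), 42 in hypothyroid control replicate 1 (others 43) and 42 in hypothyroid GC-1 replicate 3 (others 44). The median standard error of a bead mean was 4.93% in hypothyroid control replicate 1 (others 5.12% to 5.13%), and the 2 correlations of 0.941 are given above. Among 150 groups of list scores there were 11. Euthyroid GC-1 replicate 1 had -0.25 for the transport list (others -0.03 to 0.05), -1.19 for Kupffer cells (-0.06 to 0.21) and 0.31 for cholangiocytes (-0.20 to -0.11). Fatty acid synthesis was -0.29 in hypothyroid control replicate 4 (0.11 to 0.14) and fatty acid oxidation -0.31 in euthyroid control replicate 3 (0.04 to 0.16). Acute phase was 0.76 in hypothyroid GC-1 replicate 2 (0.17 to 0.25). Endothelial scores were -0.34 in euthyroid T3 replicate 1 (-0.11 to -0.03) and -0.32 in hypothyroid GC-1 replicate 4 (-0.05 to 0.00). B cell markers were at 0.042 in hypothyroid GC-1 replicate 1 (-0.30 to -0.24), pancreatic acinar markers at 5.81 in euthyroid T3 replicate 3 (-0.14 to 0.11) and skeletal muscle markers at 0.84 in euthyroid control replicate 4 (-0.27 to -0.08).

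Among 157 groups of values of target genes and of the genes of largest change there were 15 such arrays, given here as log2 signal. In euthyroid GC-1 replicate 1 Abca8a was at 5.29 (others 7.48 to 7.75), Thrsp at 11.51 (12.22 to 12.44), Dio1 at 11.80 (12.68 to 13.01), Klf9 at 12.53 (11.78 to 11.98), Gpd2 at 10.98 (9.51 to 9.70) and Slc22a7 at 9.43 (8.42 to 8.63). In euthyroid T3 replicate 1 Abca8a was at 5.53 (7.61 to 7.82), Klf9 at 12.49 (11.68 to 11.89), Slc22a7 at 9.26 (8.29 to 8.54), Sspo at 7.42 (6.17 to 6.44) and Sucnr1 at 6.58 (7.85 to 8.13). Serpina7 was at 8.91 in euthyroid control replicate 5 (7.51 to 7.76) and at 6.10 in T3 replicate 3 (5.16 to 5.42). G6pc was at 12.85 in euthyroid GC-1 replicate 2 (11.79 to 12.09) and Hectd2os at 11.34 in hypothyroid control replicate 3 (11.93 to 12.01).

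Of 113 named genes whose response was tested for a difference between the states, 24 differed for at least 1 ligand by the limma test of the difference (hypothyroid minus euthyroid, log2). Values marked as fitted have no exact size, because a group compared was below background. Of the calls of genes named for these differences, slide as a block ended 18 of 27 for GC-1 and 6 of 20 for T3, slide as a random block 13 and 3, neqc within each state 7 and 10, and the authors' values 8 each. For T3 the genes were Slc25a45 at 2.07, Ttbk1 at -1.53, Vldlr at -2.34, Cbr3 at -3.35 and Ttr at -0.90, and, as fitted values, Dio1 at 4.96, Igfbp1 at 1.68, the Alb probe at -1.17, Acot3 at -3.03, Gas7 at -3.51 and Hectd2os at -3.59. For GC-1 the positive differences were in Dio1 at 5.43 and Igfbp1 at 2.60, both fitted, Cyp7a1 at 3.20, Upp2 at 2.98, Slc25a45 at 2.08, Cyp2c29 at 1.90, Thrsp at 1.72, Acot11 at 1.66, Papss2 at 1.58, Cyp2f2 at 1.15, Stat5a at 0.97 and Apof at 0.75. The negative ones were in Hectd2os at -3.38 and Acot3 at -2.58, both fitted, Cbr3 at -2.83, Gas7 at -2.73, Acot1 at -2.70, Axin2 at -1.66, Nqo1 at -1.09, Aox1 at -0.85 and Ttr at -0.85.

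Splits of the same arrays into groups of the same sizes bear on each count. In euthyroid mice only the real one of 100 gave as many calls (467 for T3, highest other 2, and 524 for GC-1, highest other 1). In hypothyroid mice only the real one of 35 did (974, highest other 66, and 1577, highest other 0). This argues against chance but does not exclude slide. For the direct comparison of GC-1 and T3 the splits decide nothing, since any split gives at least the 0 calls found (100 of 100 in euthyroid and 35 of 35 in hypothyroid mice, highest other 1 in each; 725 and 2123 probes had an unadjusted p under 0.05 in limma). For the differences of response the splits do not settle the matter. In all, 7 of 100 splits for T3 (81 calls, highest other 900) and 6 of 100 for GC-1 (219 calls, highest other 805) gave as many, the real one included. Of the others as large, 4 for T3 and 5 for GC-1 left the hypothyroid groups as they are and so still held their response. The highest for T3 did so and also put euthyroid T3 replicate 1 with controls 1 to 4, all on slide 1, and with slide as a block the T3 count was 214. Without such splits, set apart only after their counts were seen, the highest other count was 96 for T3, above its 81, and 48 for GC-1, below its 219. For these differences the set of splits was corrected after a first count had been seen, and with the incomplete set the GC-1 share had lain on the other side of the limit. For the 2 control groups only the real split of 100 gave as many calls (12007, highest other 9217), which argues against chance but does not exclude the slide run.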

How the results depend on the processing

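Leaving out the arrays that stand apart was chosen after the data were seen, and the other settings before. Of the counts and slopes recomputed, 176 stayed within 1.5 times the reported count or within the spread and 37 did not. Unless the setting's construction is named, the cause was not tested. With slide as a block, limma called 270 probes for T3 (120 of the 467) and 97 for GC-1 (57 of the 524) in euthyroid mice, 990 between the ligands in hypothyroid mice with a slope of 1.80, and 214 and 770 for the differences of response to T3 and GC-1. By construction the euthyroid effects then rest on T3 replicate 1, the hypothyroid T3 effect on T3 replicates 1 and 2, and the hypothyroid difference between the ligands on T3 replicate 3. Slide as a random block gave 743 calls for GC-1 in hypothyroid mice and 71 for its difference of response. The replicate block, which by construction also joins control arrays of the same number, gave 717 and 763 calls for T3 and GC-1 in euthyroid mice. Whether the numbers pair arrays stays open. The block gave 503 and 1012 in hypothyroid mice, 72 and 221 for the differences of response and 11922 between the controls. Calls between the ligands did not change. Without the 2 arrays that stand apart, euthyroid T3 and GC-1 gave 1016 and 889. Without hypothyroid T3 replicate 3 too, the differences of response gave 152 and 578. For these the authors' value table gave 34 and 96, neqc within each state 35 and 117, and the contrast's groups alone 39 and 358. Between GC-1 and T3 in hypothyroid mice, no background correction gave 1, the authors' values 2, no detection filter 1 and all 26 arrays in 1 fit 20. The share of higher calls was 32.4% with the value table against 51.9% for the T3 difference, and 52.7% without background correction against 67.1% for GC-1. The controls were not compared with the value table, neqc within each state or slide as a block.

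Leaving out each array in turn gave 286 to 452 calls for T3 and 340 to 464 for GC-1 in euthyroid mice, 707 to 1003 and 978 to 2538 in hypothyroid mice, 0 in all cases between the ligands in euthyroid mice and 0 to 1 in hypothyroid mice (limma found 725 and 2123 at an unadjusted p under 0.05 with all arrays). It gave 55 to 121 and 131 to 833 for the differences of response, and 11028 to 11977 between the controls. The slopes ran from 0.976 to 1.08 and from 1.03 to 1.15. The lowest counts in euthyroid mice were those without control replicate 5 (286) and control replicate 1 (340, and 345 without control 5). For GC-1 in hypothyroid mice such counts are given above. Its difference of response gave 833 without hypothyroid control 1, and 131 and 142 without GC-1 replicates 3 and 4. Of 370 called values of named genes 222 were lost in no setting. Over 5974 alternative values of them 0 reversed and 5231 passed limma's threshold. Signal over background limits the fold changes of dim probes, and the hypothyroid arrays were dimmer.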

Other observations

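Across both states and both ligands, 106 genes were called in all 4 comparisons with controls, 64 higher and 42 lower, and 0 in mixed directions. Log2 fold changes are given in the order T3 and GC-1 in euthyroid, then T3 and GC-1 in hypothyroid mice, and the ligands of a state share their controls. Idh3a, a subunit of isocitrate dehydrogenase, was at 1.55, 1.19, 2.17 and 2.58, and Pdp2, a phosphatase of pyruvate dehydrogenase, at 1.27, 1.23, 2.04 and 2.29. Among the genes that fell were the alcohol dehydrogenase Adh4 at -1.28, -1.01, -1.96 and -1.33, the cytochrome Cyp2c23 at -1.57, -1.69, -1.14 and -1.11, the acyl-CoA thioesterase Acot4 at -1.16, -1.22, -2.56 and -1.68 and the sialyltransferase St6gal1 at -1.13, -1.37, -1.32 and -1.39. These genes were chosen after their values were seen.

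Between the states, which share no controls, 150 probes rose and 88 fell after T3 in both, where independent lists of these sizes would share 7.09 and 4.001, and 184 rose and 90 fell after GC-1, where they would share 13.3 and 7.13. Opposite calls were 0 for T3 and 1 and 2 for GC-1. Of the 467 probes called for T3 in euthyroid mice 436 had the same direction in hypothyroid mice, and of the 524 for GC-1 477 had.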
